A study of Phalacrocorax auritus with 15 samples.

How the data were processed

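RNA sequencing of left-lobe liver was carried out on 15 samples from double-crested cormorant embryos, 5 per group, exposed to dimethyl sulfoxide solvent or to ethinylestradiol at nominal doses of 3.33 or 33.3 µg per g egg. Per the labels' protocols, eggs were injected in the air cell before they were incubated. The incubator was kept at a humidity of 60% and at 37.5 °C. Liver was homogenised, RNA was extracted with a silica column kit with added DNase I digestion, and libraries were prepared with standard Illumina methods. The labels number the samples of a group as replicates and do not say that each came from a separate egg, so p-values measure the spread between these samples.

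The deposited table holds whole-number counts per feature for each library, which were taken as unnormalised because their totals differ between libraries. The aligner, the counting program, the reference and the annotation are not given in the sources used here, nor is whether a feature stands for a gene, a transcript or a group of related sequences, whether counting used strand or how reads shared by similar transcripts were assigned. Features that share reads with near-identical copies may therefore be split or merged. The feature IDs carry no gene names, and 0 of the 16181 IDs could be given one, so the 23 gene lists fixed in advance for liver, oestrogen response and cell types were not tested.

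Each column was matched to a sample by its name. A header line of the table gives each column a class of control, medium or high dose. The medium class was read as 3.33 µg/g and the high class as 33.3 µg/g, the doses in the labels, and the final digit of the column name as the replicate number. No header or label states this match in words. In all, 0 columns were left without a sample. Total counts per library ranged from 11602455 to 19929889. Counts of pairs of libraries within a group differed by more than sampling noise in every pair: the lowest chi-square per degree of freedom, over features with at least 10 counts in the pair, was 16.42, so no pair was treated as a library deposited more than once. This check does not tell repeat preparations of a sample from separate samples.

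The main test was the edgeR quasi-likelihood F-test in a single model with the 3 groups and no covariate, fitted to all 15 libraries so that the groups share an estimate of the spread. Libraries were scaled by the trimmed mean of M-values (TMM). Features were kept with the default edgeR filter by expression (minimum count 10, minimum total count 15), which left 13014. P-values were adjusted by the method of Benjamini and Hochberg over these features, and features with an adjusted p under 0.05 were called. All tests were two-sided. The standard error of a log2 fold change was its absolute value divided by the square root of F. The common biological coefficient of variation was 0.3697. CPM values are counts scaled to the library total in the usual way, and log2 CPM for principal components and correlations used the TMM scaling and a prior count of 2. Log2 fold changes of the main test used the TMM scaling, so they need not equal the ratios of the printed CPM values or shares. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

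The test was checked on simulated data with 200 of 13014 features changed by 2-fold or 4-fold, 100 of each. For 33.3 µg/g against solvent it recovered 63% and 80% of them, with 4.67% of calls false. For 3.33 µg/g against solvent it recovered 59% and 81%, with 6.67% false, and for 33.3 against 3.33 µg/g 58% and 85%, with 5.3% false. The simulated counts were drawn from the fitted model, with balanced increases and decreases and no library that stood apart. Far fewer features changed in them than were called against solvent in the real data. These rates therefore need not hold for the real data.

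The design, the test, the other settings to try and the rule for naming features were fixed before the data were examined. Because no gene names were given, the rule took, for each comparison, the 2 largest increases and 2 largest decreases by ID. Eligible features had an adjusted p under 0.05, a mean of at least 1 CPM over all libraries and every library of the exposed group on the same side of the solvent mean of log2 CPM. The increases were the same features at both doses. The decreases given by ID are those taken at 33.3 µg/g; the 2 taken at 3.33 µg/g are given by their values. No feature was eligible between doses. The features that hold the most counts in solvent or exposed livers were chosen after their values had been seen.

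Alternatives were median-of-ratios scaling, scaling by library size alone, no filter, a filter of 5 CPM in 5 libraries, DESeq2, limma-voom, a robust fit, fits of only the groups compared, the replicate number as a block, other thresholds and leaving out each library in turn. Added after seeing the data were fits without several libraries, with all libraries thinned to the lowest total, and without features that hold at least 0.1% of any library. For features with 1 count in the solvent libraries, the ratio of rates was given with an exact 95% interval from the counts. Such intervals pool the counts of a group, so they cover counting error only and leave out the spread between samples. The labels record no step that removed duplicate reads by molecular identifiers, so duplicates may also be counted. Overlap between doses was set against 20 simulated data sets in which all 3 groups were drawn from the solvent means.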

Results

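Liver transcription was profiled in embryos of the double-crested cormorant, a fish-eating colonial waterbird, after exposure in the egg to ethinylestradiol (EE2), a synthetic oestrogen used in oral contraceptives. EE2 dissolved in dimethyl sulfoxide, or the solvent alone, was injected into the air cell of the egg in a volume of 50 µl before incubation. The nominal doses were 3.33 and 33.3 µg per g egg, and the labels give actual doses of 2.3 and 31.9 µg per g egg. Left-lobe liver was profiled in 5 samples per group, giving 15 libraries. The stage is day 14 of embryonic development in the sample labels, whereas the text on the series' design gives day 16 for this species. Quail livers that the series title also mentions were not analysed here.

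Total counts per library ranged from 11602455 to 19929889. The mean total was 16920140 ± 3141062 counts in solvent livers, 16041899 ± 1312843 at 3.33 µg/g and 15490745 ± 2647481 at 33.3 µg/g (SD, n = 5 each). The table held 16181 features, of which 13014 passed the filter on low counts and were tested. The files do not pair the feature IDs with gene names, so the changes are described by abundance, direction and dose, and 4 features are given by ID.

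Solvent and EE2-exposed livers occupied separate regions of the principal component plot. On the second component, which held 28.96% of the variance, the 5 solvent libraries lay between -88.12 and -32.86, and every exposed library lay above them, the lowest at -7.112. The first component held 39.35% and spread libraries within the groups. Solvent replicate 2 was at 87.52 on it, whereas the other 4 solvent libraries were between -78.06 and -16.26. Among exposed libraries, replicate 5 at 3.33 µg/g was at 66.09, and replicates 3 and 2 at 33.3 µg/g were at 52.24 and 35.06. The rest were between -21.84 and 24.5. Replicate 5 at 3.33 µg/g held 9.409% of its counts in its 20 most abundant features, against 14.95 to 19.77% in the others at that dose. Correlations of log2 CPM (counts scaled to library size) across features, which are not independent replicates, were 0.7852 to 0.8424 between solvent replicate 2 and the other solvent libraries. Among those other 4 they were 0.9498 to 0.9832, and among the 10 exposed libraries 0.9011 to 0.9875.

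**Figure D1:**
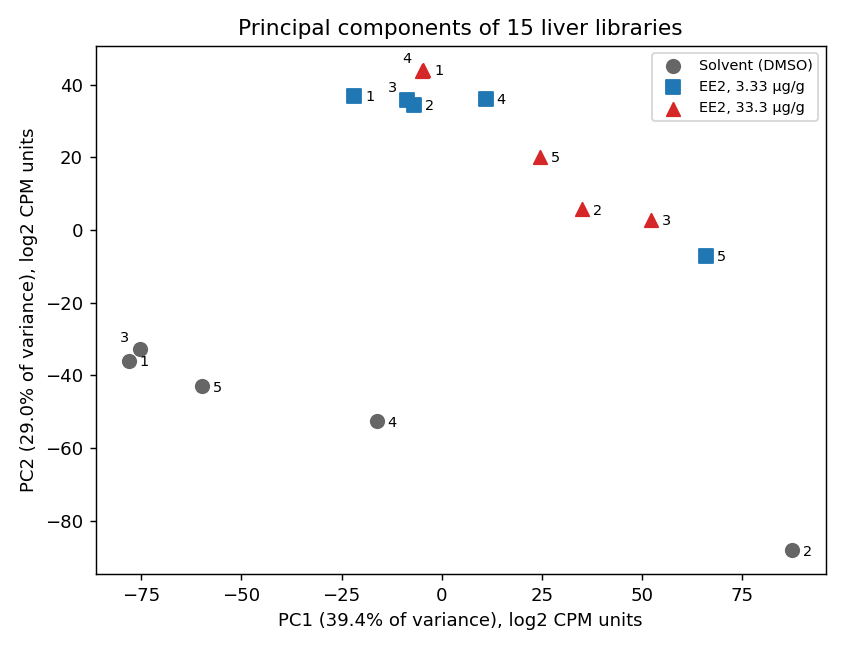
Scores of the 15 libraries on the first and second principal components of log2 CPM over 13014 features, in log2 CPM units; each point is one library, with its replicate number, coloured by group. The 10 exposed libraries lie above the 5 solvent libraries on the second component, and solvent replicate 2 lies at the far right, at 87.52 on the first.

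The comparison of the higher dose with solvent asked which hepatic RNAs responded to EE2. At 33.3 µg/g, 1725 features rose and 1875 fell, together 27.7% of those tested. Changes of at least 2-fold comprised 851 decreases and 431 increases with scaling by trimmed mean of M-values (TMM). They comprised 907 decreases and 399 increases with median-of-ratios scaling, but 352 decreases and 1000 increases with scaling by library size alone. Leaving out solvent replicate 2 gave 1079 decreases and 695 increases of that size. Of 103 features with a mean of at least 1000 CPM, 28 fell and 8 rose, and 31 and 8 with median-of-ratios scaling. These counts were 20 and 23 with library size alone and 71 and 9 without solvent replicate 2. The median log2 fold change was 0.612 among features that rose and -0.916 among those that fell.

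The largest increases in fold were from near absence to high abundance. The feature s2f_0020325001 averaged 1.503 ± 1.065 CPM in solvent livers and 14530 ± 3844 CPM at 33.3 µg/g (SD, n = 5 each), a log2 fold change of 12.59 with a standard error of 0.993 (edgeR adjusted p = 6.63e-06). It had 135 counts in the 5 solvent libraries together and at least 9930 CPM in every library at 33.3 µg/g. The feature s2f_0008026003 had 1 count in the 5 solvent libraries and averaged 179 ± 76.3 CPM at 33.3 µg/g (SD, n = 5; edgeR adjusted p = 6.63e-06). From the counts, the ratio to solvent was 15400, with a 95% interval of 2770 to 610000 that covers counting error only.

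Among the decreases, s2f_0000319012 went from 218 ± 124 CPM in solvent livers to 1.39 ± 0.449 CPM at 33.3 µg/g (SD, n = 5 each), a log2 fold change of -7.94 with a standard error of 1.09 (edgeR adjusted p = 0.000188). Solvent replicate 2 held 2.586 CPM of this feature, against 271.9 ± 35.6 CPM in the other 4 solvent libraries (SD, n = 4), and with limma-voom the log2 fold change was -6.83 with a standard error of 2.68 (adjusted p = 0.0773). The other decrease named by the rule, s2f_0022309001, came from solvent replicate 2 alone. That library had 3186 CPM, the other 4 solvent livers 0.908 ± 0.479 CPM (SD, n = 4) and the livers at 33.3 µg/g 1.25 ± 0.383 CPM (SD, n = 5). Its fitted log2 fold change was -8.64 with a standard error of 2.27 (edgeR adjusted p = 0.012), and -0.15 without solvent replicate 2 (edgeR adjusted p = 0.856).

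**Figure D2:**
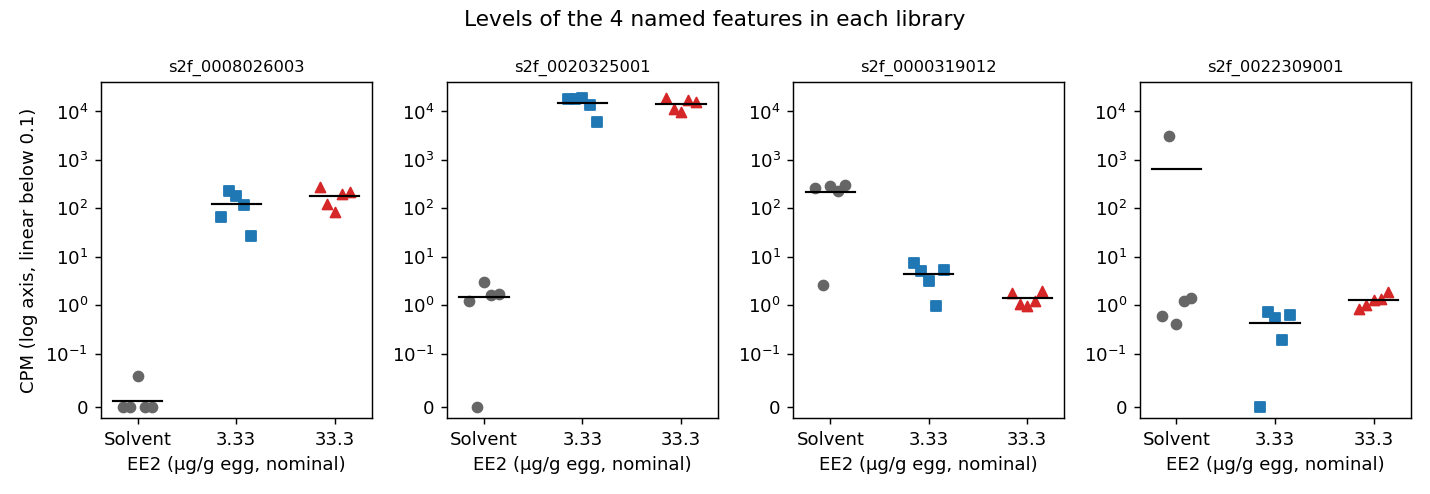
CPM of 4 features in each library (log axis, linear below 0.1), by nominal EE2 dose in µg per g egg; each point is a library and each bar the mean of 5 libraries. The 2 features on the left are at or below 2.962 CPM in solvent livers and at or above 26.76 CPM in every exposed liver; on the right, solvent replicate 2 sets the solvent mean of s2f_0022309001, at 3186 CPM, and lies below the other solvent livers for s2f_0000319012, at 2.586 CPM.

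The features holding the most counts also shifted. The feature that was most abundant in solvent livers took 8.474 ± 4.787% of their counts and 1.741 ± 0.677% at 33.3 µg/g (SD, n = 5 each). With TMM scaling its log2 fold change was -2.94 with a standard error of 1.01 (edgeR adjusted p = 0.0421). Its share was 0.0327% in solvent replicate 2 and at least 9.388% in each of the other 4 solvent livers. Without solvent replicate 2 its log2 fold change was -3.26 (edgeR adjusted p = 0.00019). The feature that was most abundant in exposed livers rose from 7141 ± 3369 CPM to 36160 ± 10410 CPM (SD, n = 5 each). With TMM scaling its log2 fold change was 1.70 (edgeR adjusted p = 0.0408). Solvent replicate 2 held 1834 CPM of this feature, against 8468 ± 1843 CPM in the other 4 solvent livers (SD, n = 4). Leaving out that library gave a smaller log2 fold change of 1.42 (edgeR adjusted p = 0.0142).

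All solvent libraries carry one column prefix in the count table and all exposed libraries the other, so any batch that the prefix marks cannot be told apart from EE2 exposure at either dose. Without solvent replicate 2 the test called 5429 features at 33.3 µg/g, of which 2710 rose and 2719 fell, and 3476 of the 3600 original calls (96.6%) were among them with the same sign. Scaling by library size alone moved the median log2 fold change of all features from 0.0224 to 0.399 and gave 2920 increases and 689 decreases. With median-of-ratios scaling this median was -0.017, with 1497 increases and 2036 decreases, and 3372 of the original calls were kept with the same sign. Directions are therefore relative to the scaling, here TMM.

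The lower dose was set against the same solvent livers. At 3.33 µg/g, 1703 features rose and 1725 fell, together 26.3% of those tested. Changes of at least 2-fold comprised 839 decreases and 340 increases. They comprised 885 decreases and 318 increases with median-of-ratios scaling, but 382 decreases and 919 increases with scaling by library size alone. Of the 103 most abundant features, 28 fell and 9 rose, and 29 and 7 with median-of-ratios scaling. These counts were 16 and 25 with library size alone and 72 and 10 without solvent replicate 2.

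At the lower dose, s2f_0020325001 and s2f_0008026003 also rose and s2f_0000319012 also fell. The abundance of s2f_0020325001 was 14934 ± 5429 CPM (SD, n = 5), a log2 fold change from solvent of 12.68 with a standard error of 0.996 (edgeR adjusted p = 7.26e-06). That of s2f_0008026003 was 125 ± 82.7 CPM (SD, n = 5; edgeR adjusted p = 8.07e-06), a ratio from the counts of 10800 with a 95% interval of 1950 to 428000. The feature s2f_0000319012 was at 4.42 ± 2.48 CPM (SD, n = 5), a log2 fold change of -6.28 with a standard error of 0.992 (edgeR adjusted p = 0.000516; limma-voom adjusted p = 0.0543). The feature s2f_0022309001 was at 0.422 ± 0.311 CPM (SD, n = 5), with a fitted log2 fold change of -10.18 (edgeR adjusted p = 0.00788) that was -1.70 without solvent replicate 2 (edgeR adjusted p = 0.0399). The largest decreases that the rule took at 3.33 µg/g were 2 other features, not given by ID. One had 18.88 ± 1.54 CPM in the solvent livers other than replicate 2 (SD, n = 4), 386.9 CPM in that library and 0.0629 ± 0.0456 CPM at 3.33 µg/g (SD, n = 5). Its log2 fold change was -10.24 with a standard error of 2.09 (edgeR adjusted p = 0.00276), and -8.73 without solvent replicate 2 (edgeR adjusted p = 0.00259). At 33.3 µg/g it reached 30.21 CPM in one library, and its log2 fold change was -3.90 (edgeR adjusted p = 0.044), or -2.39 without solvent replicate 2 (edgeR adjusted p = 0.141). The other had 1872 CPM in solvent replicate 2 and 0.670 ± 0.552 CPM in the other 4 solvent livers (SD, n = 4). Its log2 fold change at 3.33 µg/g was -12.66 (edgeR adjusted p = 0.0297). Without solvent replicate 2 it was -4.50 and the call was lost (edgeR adjusted p = 0.422). At 33.3 µg/g the log2 fold change was -1.88 (edgeR adjusted p = 0.562), but 6.28 without solvent replicate 2 (edgeR adjusted p = 0.0345). There this feature reached 430.6 CPM in one library. The most abundant feature of solvent livers took 2.06 ± 1.062% of counts at 3.33 µg/g (SD, n = 5) and did not pass the test, with a log2 fold change of -2.64 (edgeR adjusted p = 0.0644); without solvent replicate 2 it was -2.96 (edgeR adjusted p = 0.000432). The feature most abundant in exposed livers reached 34160 ± 12830 CPM (SD, n = 5). Its log2 fold change was 1.66 (edgeR adjusted p = 0.0473), and 1.37 without solvent replicate 2 (edgeR adjusted p = 0.0184).

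Without solvent replicate 2 the test called 4965 features at 3.33 µg/g, including 3242 of the 3428 original calls (94.6%) with the same sign. Scaling by library size alone moved the median log2 fold change of all features from -0.00461 to 0.379 and gave 3064 increases and 677 decreases. With median-of-ratios scaling this median was -0.0355, with 1484 increases and 1831 decreases.

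The direct comparison of the doses asked whether the higher dose changed the liver transcriptome further. No feature passed the edgeR test between 33.3 and 3.33 µg/g, where the smallest adjusted p was 0.999. At an unadjusted p under 0.05 the count was 479, or 3.68% of the features tested. The spread in this test came from all 3 groups. Solvent replicate 2 therefore entered it, although the comparison does not use that library, and widened the standard errors of some features. Without solvent replicate 2 the test between doses again called 0 features. DESeq2 called 5 features (3 higher and 2 lower at 33.3 µg/g), a fit restricted to these groups called 1, and limma-voom called 0. For s2f_0020325001 the log2 difference between doses was -0.08 with a standard error of 0.612, or 0.365 without solvent replicate 2. It was 0.48 for s2f_0008026003 (standard error 0.498, or 0.501 without that library) and 1.54 for s2f_0022309001 (2.24, or 0.577). For s2f_0000319012 it was -1.67 with a standard error of 0.913. The 2 features taken at 3.33 µg/g and not given by ID had 10.78 and 6.34, each highest at 33.3 µg/g in replicate 2. None of these passed (edgeR adjusted p = 0.999 for each).

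Many features changed at both doses. In all, 1294 features rose at both doses and 1465 fell at both, and no feature was called in opposite directions. With scaling by library size alone, 2517 rose and 566 fell at both doses, and with median-of-ratios scaling 1097 rose and 1574 fell. Lists as long as those of the main test, drawn independently, would share 225.7 increases and 248.5 decreases. The shared calls were 76.6% of those at 33.3 µg/g and 80.5% of those at 3.33 µg/g. Among these 2759 features the median absolute log2 difference between doses was 0.102, with a median standard error of 0.175, and for 83.2% of them the 95% interval of the difference lay within 2-fold. Selection of features that passed at both doses with the same sign itself favours small differences. Of the 4269 features called at either dose, 0 passed the test of the difference.

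Both comparisons used the same solvent libraries, which by itself makes fold changes correlate. Across features, log2 fold changes at the doses had r = 0.918, against 0.505 in 20 simulated data sets of unchanged groups with common controls. Their covariance was 0.753, against 0.0765 simulated, a difference of 0.677. The sign was the same for 87.1% of features, against 66.9% simulated. The simulations gave no shared calls, which was bound to follow since no feature differed in them. Each feature was drawn independently, so no simulated library stood apart over many features as solvent replicate 2 did. The simulated values therefore do not show what these particular solvent libraries would give. With the solvent libraries divided between the doses, r was 0.630 and 0.402, the covariance 0.671 and 0.494, and the shared calls 1246 and 1163. The same division without solvent replicate 2, made after seeing the data, gave r of 0.583 and 0.668, covariances of 0.714 and 0.785, and 2520 and 2746 shared calls. Without solvent replicate 2 there were 4335 shared calls with all other solvent libraries in use.

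**Figure D3:**
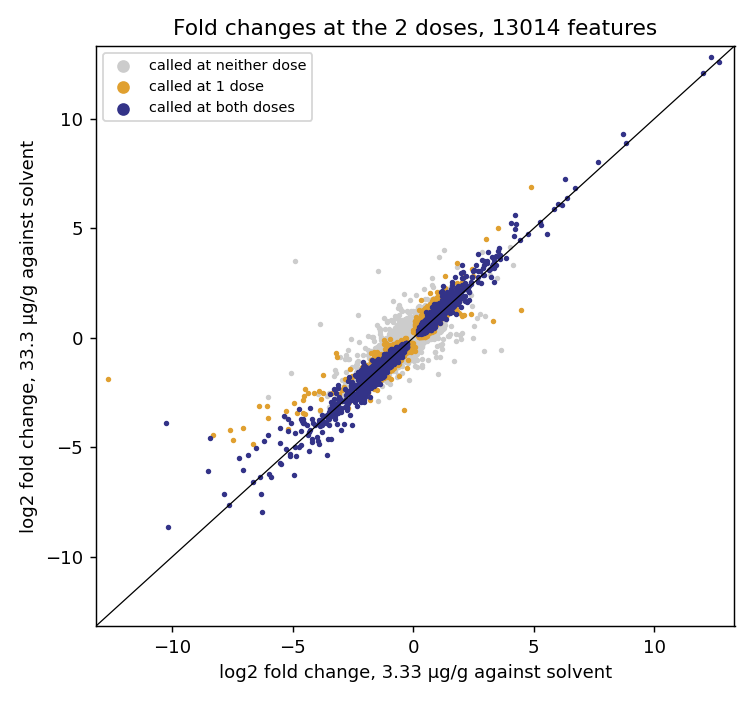
Log2 fold change against solvent at 33.3 µg/g (vertical) and at 3.33 µg/g (horizontal) for 13014 features; each point is one feature, coloured by whether it passed the test at neither, one or both doses, and the line marks equal change. The 2759 features called at both doses lie in the lower left and upper right, and none was called in opposite directions.

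Exposed and solvent livers differed without overlap at many features. In 772 features every one of the 10 exposed libraries was above all 5 solvent libraries, and in 573 every exposed library was below them, on the TMM-scaled log2 CPM. The counts were 1488 and 1801 without solvent replicate 2. Random groupings would give 0.0333% of features, or 4.33, in each direction with all libraries, and 0.0999%, or 13, without that library. Separation by at least 10-fold, a criterion chosen after the data had been seen, held for 7 features that were higher in exposed livers and 1 that was lower. The 7 features reached at most 12.9 CPM in a solvent library and lay between 26.76 and 19100 CPM in exposed libraries. Without solvent replicate 2, 9 features were higher and 13 lower by this criterion.

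Features that rose at both doses held 4.42 to 7.57% of the counts of a solvent library and 12.22 to 17.97% of those of an exposed library. Those that fell at both doses held 20.38 to 27.59% in solvent and 12.1 to 14.29% in exposed libraries. These features were selected on the same libraries, so the shares describe the size of the shift and are not a further test of it.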

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

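The splits of the samples were planned before their results were seen; the other tests of explanations in this part were chosen after the patterns had been seen. Of 33 groups of 5 values examined, 6 held a library farther from the rest than Dixon's 95% critical value of 0.71 allows, where chance gives about 1 in 20 for values not picked from the same data. The single value in solvent replicate 3, 0.05808 CPM of s2f_0008026003 where the other 4 solvent libraries had 0, is 1 count. The other 5 were all in solvent replicate 2 and are linked values of that library, not independent results. They were its TMM factor of 1.413 (next nearest 0.8547), a share of 0.03267% of counts in the feature most abundant in solvent livers (9.388%), a share of 10.04% in its own 20 most abundant features (25.58%), 3186 CPM of s2f_0022309001 (1.402) and 2.586 CPM of s2f_0000319012 (226.5).

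Solvent replicate 2 had 46 features at 100 CPM or more and over 32-fold higher than in every other solvent library, and lacked 57 features that averaged at least 100 CPM in the other 4 and were over 32-fold lower in it. The same count of lacking features was 0 in each of the other 14 libraries within their groups. Its low depth is argued against, since after thinning all libraries to one total its highest correlation with another solvent library was 0.835, below the lowest of 0.947 among the other 4; a swap with an exposed library is argued against too, since each exposed library, placed between the other 4 solvent livers (0) and the other 9 exposed livers (1) on features chosen without it and at least 4-fold apart, had a median position of 0.813 or more. A minor share of RNA from another tissue or cell type may account for the 46 features, of which 25 were also raised over 5-fold in replicate 2 at 33.3 µg/g and at most 4 in any other library, but could not remove the 57. Replacement of most of the liver RNA, or a sample from outside this set, stays open, and no biological explanation was tested, since the labels give the solvent embryos no other difference.

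The difference between solvent and exposed livers was larger than other splits of the same libraries gave. At 33.3 µg/g, 1 of 100 splits, the real one, gave as many calls as the observed 3600, and the highest other gave 2915. At 3.33 µg/g it was likewise 1 of 100, with 3428 observed and 2896 for the highest other. Of 126 possible splits 100 were run, so a share of 1 in 100 argues against chance assignment but does not exclude it. Each of the highest others swapped only 1 library per group and so kept most of the real grouping. In 6 other splits at 33.3 µg/g and 5 at 3.33 µg/g over 100 features were called, and each moved solvent replicate 2. Apart from a split with 108 calls at 33.3 µg/g, each swapped only that library with a single exposed library, which kept most of the real grouping. The remaining splits that moved it together with another solvent library gave 0 calls. Single swaps of other solvent libraries also gave 0 calls, which points to solvent replicate 2 as a structure in the samples. Neither that library nor a few dominant features account for the difference, because 5429 features were called at 33.3 µg/g without it and 3491 without the 182 features that reach 0.1% of any library. A batch marked by the column prefix stays open beside an effect of EE2: solvent and exposed libraries share 0 prefixes, so the batch and EE2 cannot be told apart.

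Between the doses 0 features were called, so all 100 of 100 splits necessarily gave as many, the highest other giving 39, and the splits say nothing on whether the doses differ.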

How the results depend on the processing

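Fits that left out several libraries or thinned the counts, and the 5-fold separation, were chosen after seeing the data. At 33.3 µg/g the count of 3600 calls moved by less than 1.5 times in 28 of 30 alternatives, the others being 1282 with a change of at least 2-fold and 5429 without solvent replicate 2. At 3.33 µg/g the count of 3428 did so in 28 of 30, the others being 1179 with at least 2-fold and 5267 without solvent replicate 2, replicates 2 and 3 at 33.3 µg/g and replicate 5 at 3.33 µg/g. With scaling by library size alone, 3609 and 3741 features were called at the higher and lower dose, of which only 2143 and 2192 were among the original calls with the same sign. With median-of-ratios scaling they were 3533 and 3315, of which 3372 and 3209 were among them. Leaving out each library in turn gave 2740 to 5429 calls at 33.3 µg/g, 2589 to 4965 at 3.33 µg/g, 2135 to 4335 at both doses and 0 between doses. The 2759 calls at both doses became 1246 and 1163 when the solvent libraries were divided between the doses, where fewer controls enter each test. Divided without solvent replicate 2, with no more controls per test, they gave 2520 and 2746 shared calls. Undivided controls without solvent replicate 2 gave 4335, so division lowered the count there too. The parts of fewer controls per test, of unshared controls and of solvent replicate 2 in the lower counts were not separated. Shared calls were 4335 without solvent replicate 2 and 4420 without the 4 libraries named above. Between doses DESeq2 called 5 features and the fit of only these groups 1, against 0 in the other 28 alternatives; the cause was not tested.

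With the replicate number as a block (replicate block) the counts were 2966, 2769, 0 and 2234 at 33.3 µg/g, at 3.33 µg/g, between doses and at both doses. No pairing by number was seen. Over 15 same-numbered pairs the correlation of deviations from the group means ran from -0.404 to 0.546, with 6 over 0.1. The mean was 0.0211, against 0.00594 for other pairs, and 4 of 15 libraries correlated best with their own number. Differently numbered libraries also shared deviations, up to r = 0.655 for replicate 5 at 3.33 µg/g and replicate 3 at 33.3 µg/g, so a pairing could be missed. The log2 fold change of s2f_0022309001 at 33.3 µg/g was 0.0079 without those 4 libraries, its level in solvent replicate 2 being the cause; at 3.33 µg/g it was -1.78 in that fit, the call again lost (edgeR adjusted p = 0.0543). Its calls were also lost with limma-voom and with the block at both doses. The calls of s2f_0000319012 were lost with limma-voom alone, where the log2 fold changes were -6.83 and -5.46 with standard errors of 2.68 and 1.93, and those of s2f_0008026003 and s2f_0020325001 under no alternative that tested them. With 5-fold in place of 10-fold separation, 11 features were higher and 4 lower in all exposed livers. Summing by gene symbol and the tests of gene lists were not run, since no symbols were given. Thinned to 11602455 counts per library, the fit called 3381 features at 33.3 µg/g and 3188 at 3.33 µg/g.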

Other observations

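Replicate 2 at 33.3 µg/g carried a trace of the features found in solvent replicate 2. The 46 features of that set summed to 28635 CPM in solvent replicate 2, or 2.86% of its counts, to 1723 CPM in replicate 2 at 33.3 µg/g, and to between 145 and 429 CPM in the other 13 libraries. The 57 features that solvent replicate 2 lacked took 23.8% of the counts of the other 4 solvent livers on average and 0.098% of its own, and 21 of them averaged at least 1000 CPM in those livers. This set, chosen without the exposed libraries, summed to 29566 to 97792 CPM in them, against 211040 to 256140 CPM in the other 4 solvent livers. The other 1123 features of at least 100 CPM had a median log2 ratio of 0.0774 in solvent replicate 2 to the other solvent livers. Solvent replicate 2 was also placed between the other 4 solvent livers (0) and the 10 exposed livers (1), on 85 features that separated those groups by at least 4-fold without it. Its median position was 0.145 on the 13 features higher in exposed livers and 0.908 on the 72 lower in them.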
